A study of Homo sapiens with 4 samples.

How the data were processed

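The series compared ribosome footprints and matched RNA in SNU-668 cells, an established human gastric cancer line. Per the labels' protocols, lysates were treated with RNase, single ribosomes were isolated on sucrose, and the protected fragments were ligated to adapters, reverse transcribed and amplified by PCR. The 2 RNA libraries carry the same protocol text, so how the RNA libraries were made, and whether they keep strand, is not given in the sources used here. There were 4 libraries, 1 in each of 4 groups: footprints and RNA from cells labelled ALKBH3 knockdown, and footprints and RNA from cells with the control shRNA. Groups were taken from the genotype labels and the assay from the titles.

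The submitters' processing notes name FastQC, cutadapt, Bowtie and STAR, without versions or roles, and the hg19 genome. The deposited counts are whole-number read counts for 16692 genes, each with an Ensembl identifier, a symbol, a biotype and a stranded hg19 span. Which counter made them, and how multi-mapping reads and strand were treated, is not given in the sources used here. The authors also deposited RPKM values (reads scaled by gene length and library depth) for the same libraries, and a ratio per gene of footprint RPKM to RNA RPKM as translational efficiency. That deposited ratio is listed at 0 wherever the RNA count is 0. The RPKM values of the footprint libraries scale with the counts by 1 constant, which between libraries is 1.05, against 1.01 for the column totals. Between the RNA libraries the corresponding factor runs from 0.403 to 1.60 over genes. Of the gene identifiers, 16248 matched the current gene name table, which served only to find list members under older symbols.

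From the counts, log2 ratios of the knockdown-labelled over the control library were computed within each assay, with a prior count of 0.5 and totals scaled by TMM factors from edgeR 4.0.16 in R 4.3.3. Totals were 554075 (control) and 689375 (knockdown-labelled) RNA counts, and 3795680 and 3742513 footprint counts. TMM factors were 0.958 and 1.04 for RNA and 0.977 and 1.02 for footprints. The change in footprints over RNA, the translational efficiency of the design, was the footprint change minus the RNA change. With 4 libraries and 4 coefficients, an interaction model leaves no residual degree of freedom and was not fitted. Each 95% interval comes from the counting error of the 2 (or 4) counts. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. No difference here has a replicate check, no p-value is given, and each comparison is between libraries, not conditions.

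Genes needed 100 reads summed over the 2 libraries of an assay, in both assays for footprints over RNA. This left 1311 genes for RNA, 7050 for footprints and 381 for footprints over RNA. A gene was counted as 2-fold apart when its log2 ratio was at least 1 in size and its interval left out 0. For each of 41 gene lists with at least 5 measured members, the median log2 ratio was set against 10000 random lists of the same size, matched on mean count in 20 bins. A list below the 2.5th or above the 97.5th percentile is said to stand apart. Over 35 lists measured in the footprints, 1.8 would do so by chance if each were a random draw of genes. The lists share members, and random lists do not measure the spread between replicate libraries. ALKBH3 is given as counts per 1000000 of the scaled total (CPM) with exact Poisson intervals, and a count of 0 allows up to 3 counts.

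Genes were named by a rule set before the data were examined: ALKBH3; for each quantity, the 8 protein-coding genes furthest in each direction by the interval bound nearest 0; 12 genes of ferroptosis, iron and stress regulation; and up to 4 members of each list described, by the same ranking. Some genes that the rule names, and 1 list within the random range, are not reported here. The gene lists and the alternatives were also set then, unless said otherwise. Alternatives were totals without TMM, median-of-ratios size factors (DESeq2 1.42.0), the deposited RPKM with 0.1 added, filters of 20 and 1 reads, no mitochondrially encoded genes, protein-coding genes alone, a 1.5-fold minimum difference, a prior count of 5, unmatched random lists, and the mean in place of the median. A further alternative, chosen after seeing the data, kept only genes whose span overlaps no listed gene on the opposite strand.

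The procedure was tested on simulated counts, drawn with counting error only from a shared profile per assay. Coverage and calls among unchanged genes thus check the calculation, not the spread between real libraries. In the real footprints the log2 ratios had a standard deviation of 0.362, against a median counting error of 0.145. In the simulated footprints (7043 genes), 100% of 90 genes set 1.5 apart on the log2 scale were counted, no unchanged gene was, and intervals covered the set value for 95.2% of genes. In the simulated RNA (1298 genes), 96.7% of 90 such genes were counted and coverage was 95.1%. For footprints over RNA (369 genes), 98.4% of 63 genes set at least 1.5 apart were counted, with 1 unchanged gene, and coverage was 94.3%. Of 200 unchanged simulated lists of 25 genes, 6.0% stood apart, as did 100% of 50 lists shifted by 0.3. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.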

Results

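Ribosome footprints, the mRNA fragments protected by translating ribosomes, and RNA were counted per gene in SNU-668 gastric cancer cells described as resistant to erastin, a compound that blocks cystine uptake and triggers the iron-dependent cell death called ferroptosis. The library names carry RLS3 in place of erastin, a mismatch the labels do not settle, so the compound behind the resistance is uncertain. Cells carried an shRNA against ALKBH3, a dioxygenase that removes methyl groups from alkylated DNA and RNA, or a control shRNA. Each assay had 1 library per condition. The footprint libraries held 3795680 counts (control) and 3742513 (knockdown-labelled) over 12049 and 12153 genes. The RNA libraries held 554075 and 689375 counts over 8538 and 10731 genes. There were no replicates, so each interval is a 95% counting interval and each difference is between single libraries.

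ALKBH3 was examined first, as a check of the knockdown label. The gene (ENSG00000166199, chromosome 11, 43902389 to 43941762 on the plus strand, hg19) had 14 footprints in the control library, or 3.78 CPM (interval 2.06 to 6.33). It had 22 footprints in the library labelled ALKBH3 knockdown, or 5.74 CPM (3.60 to 8.70). The log2 ratio was 0.59 (-0.37 to 1.54), from counts under the filter of 100 reads. Counted footprints of the targeted gene were thus not lower in the library labelled as its knockdown. The interval holds 0 and reaches down to a ratio of 0.78, so a small fall is not excluded. RNA counts of ALKBH3 were 0 in both RNA libraries, which allows up to 5.65 CPM in the control and 4.17 CPM in the knockdown-labelled library, and no RNA ratio is given. These limits hold for counts in that row and bound no mRNA level, since 3284 of 7044 protein-coding genes with at least 100 footprints also had 0 control RNA counts. ALKBH3-AS1, on the opposite strand, had 2 and 0 RNA counts. The label was thus not borne out by footprints and could not be checked in RNA, and every direction below is between the library labelled ALKBH3 knockdown and the control library.

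The first comparison asked which genes carried more or fewer ribosome footprints in the knockdown-labelled cells. Of 7050 genes, 62 were at least 2-fold higher and 30 at least 2-fold lower in the knockdown-labelled library. By the interval bound nearest 0, the 8 leading higher genes were the mitochondrially encoded MT-ND3, MT-ND5 and MT-CO2, and ASNS, TRIB3, CTH, PSAT1 and SLC7A5. The cytosolic chaperones HSPA1B, HSPA1A and HSPH1 led the lower ones. ASNS, which makes asparagine, went from 492 to 2068 footprints (log2 ratio 2.02, interval 1.88 to 2.17). TRIB3, a stress-induced pseudokinase, went from 471 to 1507 (1.63, 1.48 to 1.78). CTH, which makes cysteine from cystathionine, went from 72 to 252 (1.75, 1.38 to 2.13). PSAT1, of serine synthesis, was at 1.44 (1.31 to 1.57), and SLC7A5, a transporter of large neutral amino acids, at 1.38 (1.29 to 1.47). Of the lower genes, IL8, a chemokine, went from 2185 to 947 (-1.25, -1.36 to -1.14), GPX3, a secreted glutathione peroxidase, from 102 to 32 (-1.70, -2.27 to -1.14), and C1orf122 from 116 to 36 (-1.72, -2.26 to -1.19). Library scaling moved the split of these calls: totals without TMM gave 81 higher and 21 lower, and the deposited RPKM 92 and 19.

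**Figure D1:**
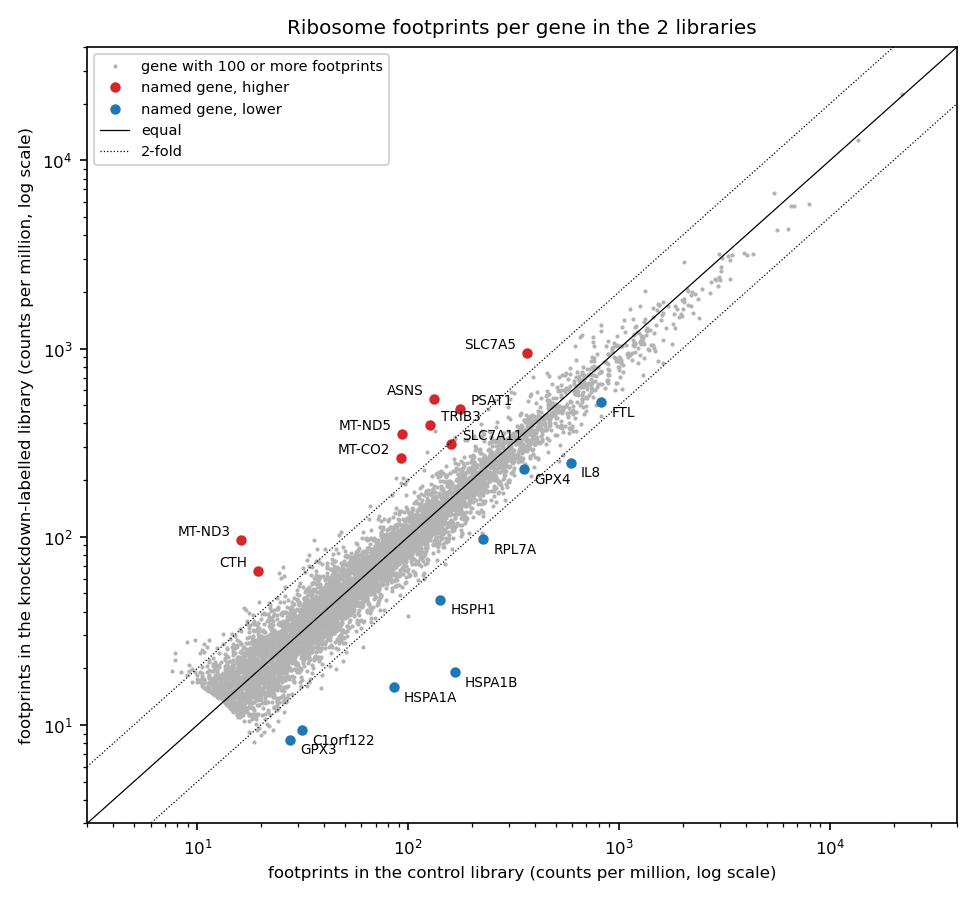
Footprints per gene in the control library (x axis) and the knockdown-labelled library (y axis), both in CPM on log scales, for genes with 100 or more footprints over the 2 libraries. Solid and dotted lines mark equal and 2-fold different values; red and blue points are named genes, with ASNS at a log2 ratio of 2.02 and HSPA1B at -3.11.

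Genes driven by ATF4, the transcription factor of the integrated stress response, were higher as a group. Their median log2 ratio was 0.91 over 28 measured members, above all 10000 matched random lists, whose central 95% ran from -0.19 to 0.09. Intervals lay above 0 for 23 members, below 0 for 0 members, and held 0 for 5, and 9 members were at least 2-fold higher. ASNS, CTH, TRIB3 and PSAT1 led the members by the interval bound nearest 0. ATF4 itself went from 52 to 83 footprints (0.62, 0.13 to 1.12), and CHAC1, a glutathione-degrading ATF4 target, from 22 to 66, under the count filter.

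Cytosolic chaperones were lower as a group. The median over 19 measured members was -0.71, below the random-list range of -0.23 to 0.10, with 17 intervals below 0, 0 above and 2 holding 0. HSPA1B, an inducible HSP70 (ENSG00000204388, chromosome 6, 31795512 to 31798031, plus strand), went from 615 to 73 footprints (-3.11, -3.46 to -2.76). HSPA1A, its near-identical neighbour, went from 316 to 61 (-2.41, -2.80 to -2.02), and reads of the pair cannot be assigned with certainty. HSPH1, an HSP110 chaperone, was at -1.61 (-1.86 to -1.36) and DNAJB1, an HSP40 co-chaperone, at -1.05 (-1.16 to -0.94). The list also holds HSF1 and HSF2, which are transcription factors, and HSPD1, a mitochondrial chaperone.

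Proteins encoded by mitochondrial DNA had more footprints in the knockdown-labelled library, with a median of 1.26 over 9 measured members, all of them at least 2-fold higher. MT-ND3 went from 60 to 368 (2.56, 2.17 to 2.95), MT-ND5 from 345 to 1342 (1.91, 1.74 to 2.08), MT-CO2 from 341 to 999 (interval 1.33 to 1.68) and MT-ND1 from 94 to 264 (1.44, 1.10 to 1.78). The 13 genes together took 0.067% of the control and 0.185% of the knockdown-labelled footprints. Nuclear-encoded respiratory chain subunits had a median of 0.02 over 60 members (random range -0.14 to 0.06), with UQCR10 at 1.02 (0.88 to 1.15), ATP5I at -0.89 (-1.06 to -0.71), ATP5F1 at 0.69 (0.51 to 0.87) and UQCRQ at 0.64 (0.48 to 0.80). Mitochondrial ribosomal proteins had a median of -0.10 over 56 members.

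**Figure D2:**
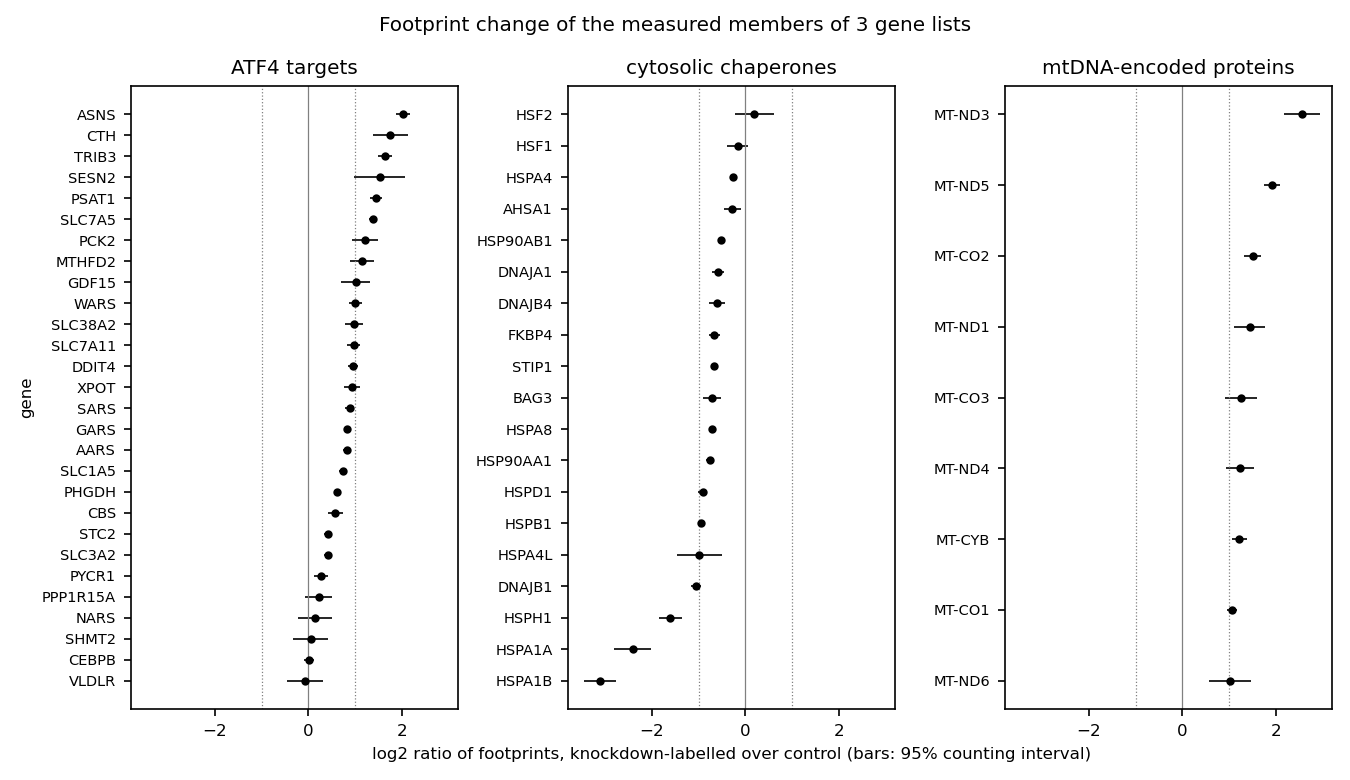
Log2 ratio of footprints, knockdown-labelled over control (x axis), for each measured member of the ATF4 target, cytosolic chaperone and mitochondrial DNA-encoded lists; bars are 95% counting intervals and dotted lines mark 2-fold. ASNS lies at 2.02, HSPA1B at -3.11 and MT-ND3 at 2.56.

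Genes of ferroptosis were examined because the series text describes the cells as erastin-resistant. Genes that limit lipid peroxidation or supply its substrates had a median of 0.18 over 25 members, above the random range of -0.20 to 0.10, with 12 intervals above 0, 5 below and 8 holding 0. None was at least 2-fold apart, and without the 3 members shared with the ATF4 and chaperone lists the median was 0.16 (random range -0.20 to 0.11). SLC7A11, the cystine transporter that erastin blocks, went from 593 to 1196 footprints (0.97, 0.82 to 1.11), and SCD, a fatty acid desaturase, from 1451 to 2699 (0.85, 0.76 to 0.94). GPX4, the peroxidase that reduces lipid peroxides, was at -0.63 (-0.76 to -0.51) and HSPB1, a small heat shock protein, at -0.95 (-1.01 to -0.88). FTL, the ferritin light chain, was at -0.66 (-0.74 to -0.58), while FTH1, the heavy chain, had 0 and 2 footprints and many pseudogene copies. AIFM2, a ubiquinone reductase, was at -0.32 (-0.56 to -0.08), NFE2L2, the antioxidant regulator NRF2, at 0.46 (0.33 to 0.60), and HMOX1, heme oxygenase, at -0.07 (-0.45 to 0.30).

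Genes reported to favour ferroptosis did not stand apart, with a median of 0.03 over 19 members. ACSL4, which loads polyunsaturated fatty acids into lipids, was at 0.17 (0.06 to 0.28), TFRC, the transferrin receptor, at -0.39 (-0.55 to -0.23) and VDAC3 at -0.56 (-1.02 to -0.11). Genes of fatty acid synthesis, desaturation and elongation stood above, at 0.28 over 18 members (12 intervals above 0 and 4 below), with ELOVL1 at 0.64 (0.52 to 0.75), ACSL5 at 0.67 (0.41 to 0.93) and FADS2 at 0.57 (0.39 to 0.75). The synthesis enzymes FASN, at -0.36 (-0.43 to -0.28), and ACLY, at -0.18 (-0.25 to -0.11), singled out after their values were seen, lay below 0. SCD, FADS2, ACSL3 and MBOAT2 are also on the list of genes that limit lipid peroxidation or supply its substrates. Selenoproteins stood below, at -0.23 over 15 members (3 intervals above 0 and 6 below), with GPX1 at -0.62 (-0.81 to -0.42) and C11orf31 at -1.19 (-1.73 to -0.66). Iron metabolism genes stood above at 0.15 over 18 members and the percentile 97.7, but not under 6 of 10 alternatives, and 12 of their intervals held 0.

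Ribosomal proteins and genes of cell division were lower. Proteins of the large cytosolic subunit had a median of -0.28 over 31 members, 21 of them with intervals below 0 and 1 above. RPL7A was at -1.23 (-1.40 to -1.05), RPL18 at -1.10 (-1.28 to -0.93) and RPLP0 at -0.75 (-0.90 to -0.59). The small subunit was at -0.28 over 21 members (12 intervals below 0 and 4 above), with RPS19 at -0.95 (-1.08 to -0.83). Ribosomal protein genes have many processed copies, so their counts are uncertain. DNA replication genes had a median of -0.31 over 29 members (19 intervals below 0 and 1 above), with MCM10 at -0.77 (-1.04 to -0.50) and RRM2 at -0.55 (-0.68 to -0.43). Mitotic genes were at -0.27 over 36 members (24 below and 2 above), with CDC20 at -0.65 (-0.75 to -0.55) and TACC3 at -0.71 (-0.93 to -0.49). Glycolysis and hypoxia-induced genes were at -0.25 over 29 members (18 below and 3 above), with TPI1 at -0.76 (-0.81 to -0.70) and CA9 at -0.60 (-0.70 to -0.50). Of 35 lists measured, 9 stood above and 8 below the random lists.

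**Figure D3:**
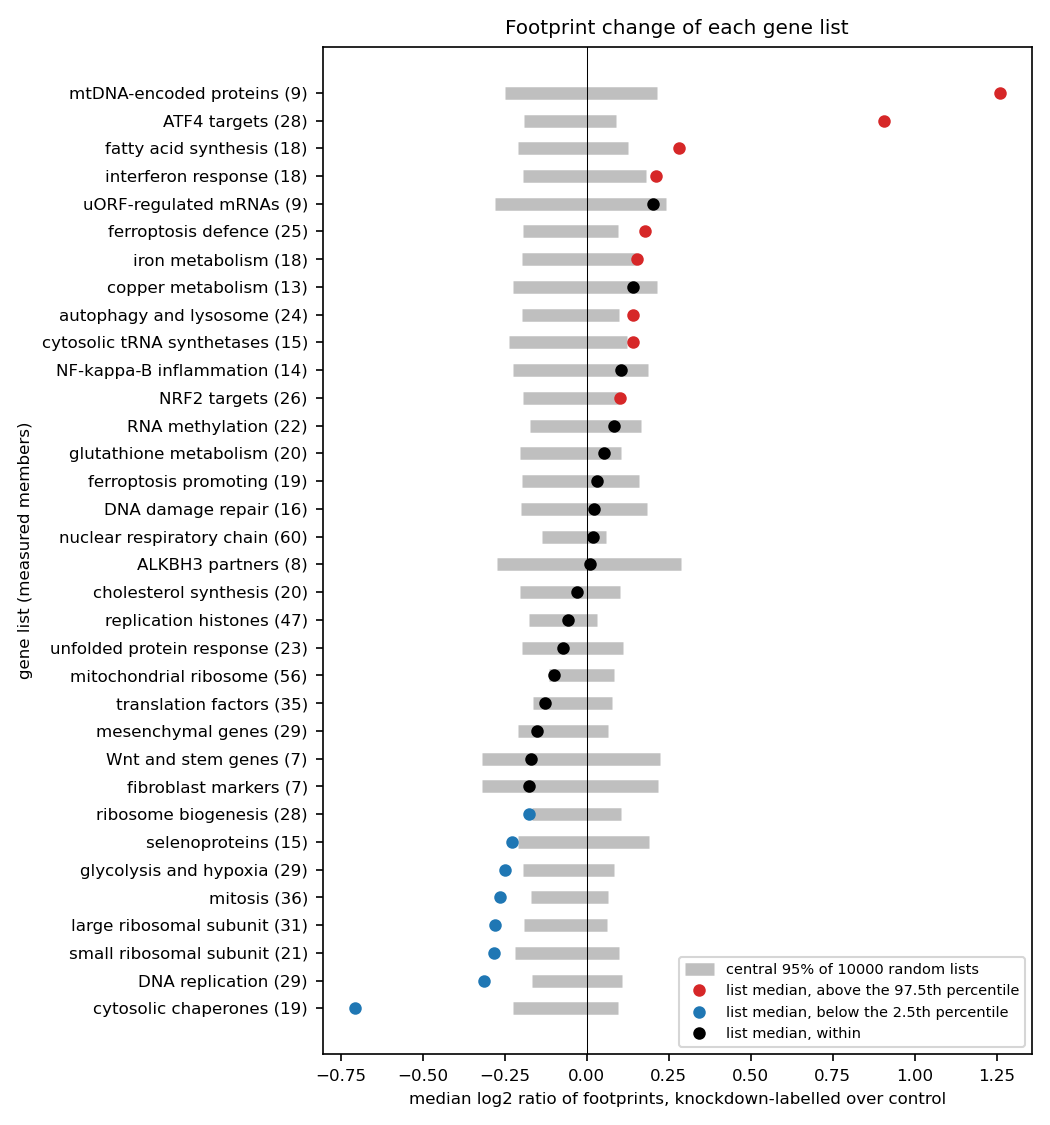
Median log2 ratio of footprints, knockdown-labelled over control (x axis), of the gene lists reported here with at least 5 measured members (y axis, with their number); grey bars are the central 95% of 10000 random lists matched on mean count. The mitochondrial DNA-encoded list lies at 1.26, ATF4 targets at 0.91 and cytosolic chaperones at -0.71.

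The second comparison asked which RNAs differed. Of 1311 genes, 38 were at least 2-fold higher and 17 at least 2-fold lower in the knockdown-labelled library. The split turned with scaling: totals without TMM gave 57 higher and 5 lower, the deposited RPKM 43 and 5, and median-of-ratios size factors 28 and 36. PTMS, which encodes parathymosin, went from 57 to 298 counts (1.94, 1.53 to 2.35), KRT81, a hair keratin, from 30 to 156 (1.92, 1.36 to 2.48), COL5A1, a fibrillar collagen chain, from 43 to 184 (1.65, 1.17 to 2.12) and TPM2, a tropomyosin, from 25 to 109 (1.67, 1.04 to 2.29). FLNA, an actin crosslinker, was at 1.43 (0.98 to 1.89) and MYH9, non-muscle myosin, at 1.33 (0.89 to 1.77). TAF9B, a transcription factor subunit, was at -1.11 (-1.39 to -0.83), STAB1 at -1.12 (-1.45 to -0.78), KRR1 at -0.93 (-1.09 to -0.77) and UBXN11 at -0.91 (-1.03 to -0.79). Proteins of the large ribosomal subunit had a median of 0.98 over 7 members, among them RPL13A at 1.58 (0.98 to 2.18) and RPL26 at 1.30 (0.71 to 1.88). Mitochondrial DNA-encoded proteins had a median of 0.39 over 12 members, but their summed RNA went from 31221.9 to 26946.4 CPM, since MT-ND6, which held 12494 of 16580 control counts, was at -0.40 (-0.43 to -0.36).

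RNA counts did not follow footprint counts. Across the 16692 genes, which are not independent replicates, Spearman's correlation of RNA with footprint counts was -0.083 in the control and -0.026 in the knockdown-labelled libraries, against 0.981 between the 2 footprint libraries and 0.763 between the 2 RNA libraries. Genes of antisense biotype took 46.0% and 42.5% of the RNA counts and 0 footprints. Of 7044 protein-coding genes with at least 100 footprints, 94.6% had under 100 RNA counts over both libraries. GAPDH had 63 and 160 RNA counts beside 10913 and 8282 footprints, while RP5-940J5.9, a feature inside its span on the opposite strand (chromosome 12, 6646960 to 6647536), had 38282 and 32532 RNA counts. Among 5281 genes whose span overlaps a listed gene on the opposite strand, RNA counts correlated with the gene's own footprints at -0.209 (control) and -0.179, and with the footprints of the opposite-strand partner at 0.448 and 0.440. Part of this gap is built in, since genes of antisense biotype had no footprints of their own. Among the 11411 genes without such an overlap, RNA counts correlated with own footprints at 0.096 (control) and 0.17. In 171 genes with at least 5000 footprints and no such overlap, RNA counts summed to 2220 and 5320, a ratio of 2.40 where the totals differ by 1.24. Their median log2 RNA ratio was 0.84, from medians of 4 and 11 counts per gene. The 0.98 of the large ribosomal subunit in RNA was thus near a rise not particular to ribosomal proteins. PTMS, KRT81, COL5A1, TPM2, FLNA, MYH9 and RPL13A above had between 25 and 57 RNA counts in the control library. STAB1, lower above, had 181 and 113 RNA counts beside 1 and 0 footprints, and UBXN11 1345 and 968 beside 69 and 54. KRR1 had 725 and 515 RNA counts beside 156 and 191 footprints, and TAF9B 260 and 163 beside 100 and 130. Whether these RNA counts come from the named genes was not tested.

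**Figure D4:**
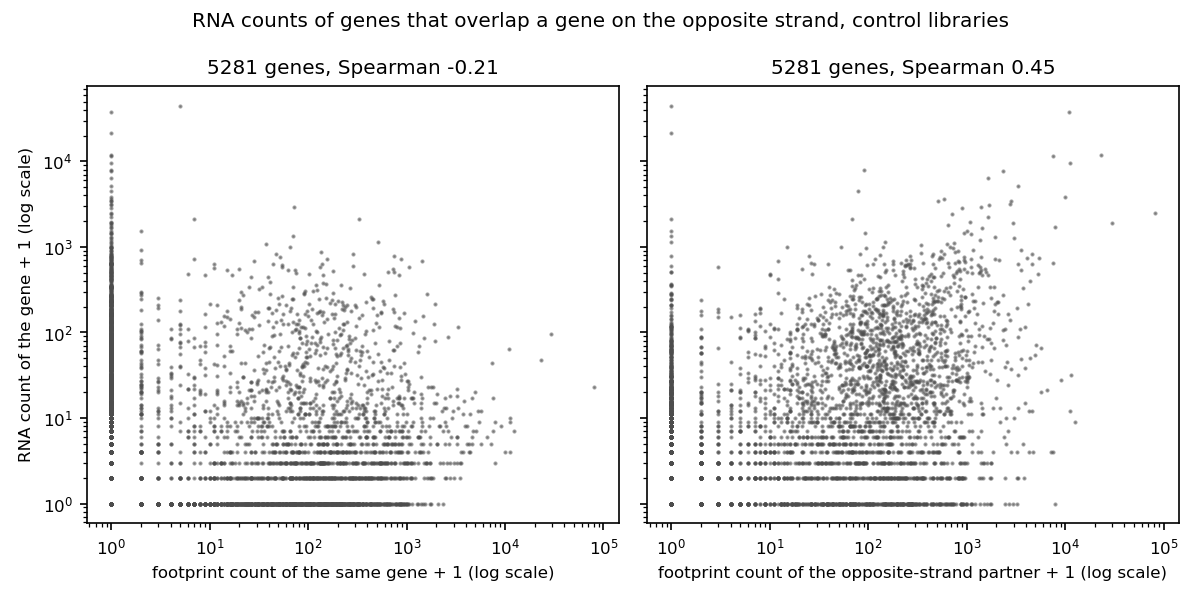
RNA count of each of 5281 genes in the control library (y axis, log scale, 1 added) against the control footprint count (x axis, log scale, 1 added) of the same gene (left) and of its opposite-strand partner with most footprints (right). Spearman's correlation across genes is -0.21 on the left and 0.45 on the right.

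The comparison of footprints over RNA, which the design names translational efficiency, covered 381 genes and inherits these RNA counts. Of them, 24 were at least 2-fold higher and 38 at least 2-fold lower in the knockdown-labelled library. PTMS was at -3.23 (-3.83 to -2.64), TPM2 at -2.50 (-3.12 to -1.87), RPS19 at -2.43 (-3.05 to -1.81) and COL5A1 at -1.95 (-2.43 to -1.47). MT-ND3 was at 2.17 (1.71 to 2.64), MT-ND5 at 1.71 (1.53 to 1.90) and TAF9B at 1.44 (0.97 to 1.91). Mitochondrial DNA-encoded proteins had a median of 1.16 over 9 members, with all 9 intervals above 0, and stood above random lists under the 9 settings run. The large ribosomal subunit had a median of -1.19 over 5 members. At the same median, it did not stand apart among genes without an opposite-strand overlap, a setting chosen after seeing the data. Across the 381 genes, RNA and footprint changes correlated at -0.113 (Spearman) and -0.134 (Pearson), and RNA changes with the changes in footprints over RNA, which contain them, at -0.782 and -0.826. In the authors' deposited table the ratio for GAPDH was 1573.1 in the control and 621.1 in the knockdown-labelled cells, that for BEST1 0.002 and 0, and that for ASNS 0 and 7924.5, with 11370 of 16692 genes listed at 0 in the control.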

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

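Leaving out replicates could not be run with 1 library per group, ALKBH3 RNA and footprints over RNA gave no ratio under any setting, and the mitochondrial list has no value without its genes. The ALKBH3 footprint ratio ran from 0.59 to 0.71 over the scalings, read filters and gene sets tried. ATF4 targets (0.82 to 1.02), chaperones (-0.88 to -0.59) and mitochondrial DNA-encoded genes (1.26 to 1.49) stood apart from random lists under all settings run. Another scaling turned the sign of COL6A3 (-0.10) and HSP90B1 (-0.09) in the footprints. Scaling moved the median RNA change of all genes from -0.13 to 0.00 (totals, RPKM) or -0.24 (size factors), the footprint median from -0.02 to 0.10 (RPKM) and that of footprints over RNA from 0.04 to 0.17 (size factors). Genes past the filter numbered 1311 in RNA, 381 in footprints over RNA and 7050 in footprints.

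Genes at least 2-fold lower in RNA were 5 with plain totals and with RPKM, 36 with size factors and 10 among protein-coding genes, and in footprints 19 with RPKM. Counts higher and lower at 20 reads were 270 and 91 (RNA), 201 and 111 (footprints) and 74 and 265 (footprints over RNA). At 1 read they were 352 and 173, 222 and 144, and 141 and 395. The numbers grew since more genes were tested, which does not account for shifts in the split. In footprints over RNA the higher share of the calls fell from 38.7% to 21.8% at 20 reads and 26.3% at 1 read. With a 1.5-fold minimum they were 110 and 141, 345 and 326, and 67 and 69. The larger numbers follow by construction, but the split does not. The higher share moved from 69.1% to 43.8% (RNA), 67.4% to 51.4% (footprints) and 38.7% to 49.3% (footprints over RNA). Without opposite-strand overlaps, chosen after seeing the data, RNA gave 21 and 3 and footprints over RNA 12 and 28, from fewer genes. The higher share of the RNA calls rose there from 69.1% to 87.5%, and the cause of that shift was not tested. The correlation of changes was 0.00 at 1 read and -0.213 without overlaps. Iron metabolism no longer stood apart at 20 reads (0.139), at 1 read (0.169), without mitochondrial genes (0.154), without overlaps (0.169), with unmatched lists (0.154) or as a mean (0.080). The same held for tRNA synthetases at 1 read (0.111) and unmatched (0.139), NRF2 targets without overlaps (0.048) and unmatched (0.101), interferon genes without overlaps (0.212) and as a mean (0.150), ribosome biogenesis without overlaps (-0.113) and as a mean (-0.137), autophagy unmatched (0.140) and as a mean (0.081), and the large ribosomal subunit in footprints over RNA without overlaps (-1.191). Mitochondrial ribosomal proteins came to stand apart at 20 reads (-0.135), at 1 read (-0.120), without overlaps (-0.135) and as a mean (-0.123), and inflammatory genes at 20 reads and 1 read (0.235 each). Where no reason is given, the cause was not tested.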

Other observations

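Tests of natural antisense RNA, of both mitochondrial explanations and of ALKBH3 counting error were chosen after the result was seen. Mesenchymal genes held far more footprints than epithelial ones: the mesenchymal list (32 genes) summed to 51627.6 CPM in the control and 50056.8 CPM in the knockdown-labelled library, and the epithelial list (19 genes) to 388.8 and 493.9 CPM. THBS1, a matrix glycoprotein, had 81052 and 86422 footprints, COL6A3, a collagen VI chain, 50539 and 48881, and COL1A2, a collagen I chain, 24916 and 21822, while of the epithelial list TJP1 had 627 and 893, KRT18 462 and 538, PKP3 259 and 340, EPCAM 0 and 2 and KRT19 4 and 3. KRT8, also on the epithelial list, had 17 and 15 footprints beside 208 and 511 RNA counts, and whether keratin footprints were undercounted was not tested. COL1A2, TJP1, KRT18 and PKP3 fall under the naming rule by their footprint changes. THBS1, COL6A3 and KRT8 fall under it only by changes in RNA or in footprints over RNA. That rule ranks changes, not footprint counts, and EPCAM and KRT19 were chosen after their values were seen. The fibroblast list summed to 22910.5 and 20627.5 CPM and the gastric lineage list to 26.2 and 32.6 CPM. TIE1, an endothelial receptor, had 1009 and 844 footprints.

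Further lists stood apart in the footprints, each with the call lost under 2 of 10 alternatives. Autophagy and lysosome genes were at 0.14 over 24 members (11 intervals above 0 and 5 below), with CTSD, a lysosomal protease, at 0.53 (0.47 to 0.58) but GABARAPL2 at -0.60 (-0.93 to -0.28). Interferon-stimulated genes were at 0.21 over 18, with IRF1 at 0.81 (0.47 to 1.14) but IFI6 at -0.80 (-0.98 to -0.62). NRF2 targets were at 0.10 over 26, a call lost (0.10, percentile 96.9) without the 1 member shared with the ATF4 list. Cytosolic tRNA synthetases were at 0.14 over 15, and at 0.03 without the 5 that are also ATF4 targets. Ribosome biogenesis genes were at -0.18 over 28 (11 intervals below 0 and 7 above), with NOP16 at -0.90 (-1.20 to -0.61). Lists within the random range were translation factors (-0.13), unfolded protein response (-0.07), replication histones (-0.06), cholesterol synthesis (-0.03), RNA methylation (0.08), partners of ALKBH3 (0.01), DNA repair (0.02), glutathione metabolism (0.05), copper metabolism (0.14), mRNAs regulated by upstream reading frames (0.20), inflammatory genes (0.11), mesenchymal genes (-0.15), Wnt and stem cell genes (-0.17) and fibroblast markers (-0.18). The AlkB family, epithelial, gastric, leukocyte, endothelial and red cell lists had under 5 measured members; in the first, ALKBH7 was at -0.64 (-0.93 to -0.35).

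RNA counts that do not follow footprints were weighed first. Too few reads do not account for it: control footprints thinned to the control RNA total still correlated at 0.962 with the other footprint library. For genomic DNA or unspliced RNA, RNA counts did not rise with gene span, at a correlation of -0.115 (control, 11411 genes without an opposite-strand overlap). Reads counted over exons alone need not rise with span, and the counter is not given, so this test cannot decide for such counts. Natural antisense RNA beside normally counted mRNA is argued against by the 0.401% of control RNA counts in genes that hold 24.7% of the footprints. A candidate explanation is that RNA reads were counted on the strand opposite to the gene, since the partner correlation exceeded the own correlation by at least 0.619 in both libraries, and MT-ND6, on the other mitochondrial strand from its 12 neighbours, took 12494 of 16580 mitochondrial RNA counts. Part of the 0.619 is built in, since genes of antisense biotype had no footprints of their own. Counting on the opposite strand would need RNA libraries that keep strand, and the kit is not given in the sources used here. The 0.401% above, and 0.772% in the knockdown-labelled library, argue against libraries blind to strand. Reads of those genes would then be counted whichever strand was used. RNA changes followed the partner's footprint changes only weakly (0.1, bootstrap interval 0.007 to 0.184, over 528 features), short of the 0.3 set beforehand.

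Higher ATF4 target and lower chaperone footprints were weighed next. Removing a smooth trend with gene length left the medians at 0.887 and -0.738, and one with abundance at 0.956 and -0.609, so neither trend accounts for them. A difference in RNA level stays open: RNA counts at opposite-strand features had medians of 0.371 for 5 ATF4 targets (PYCR1 and SLC7A11 below 0) and -0.374 for 3 members of the chaperone list (FKBP4 -0.41, HSPA4L 0.03 and HSF1, a transcription factor, whose value is the median), past the bounds of 0.3 and -0.3 set beforehand. These were taken as too few and too mixed to decide, a minimum of 5 being applied only after the values were seen, and the reading also rests on the strand hypothesis. ALKBH3 knockdown, culture conditions and a swapped or ineffective label may each underlie the pattern and cannot be told apart with 1 library per group. For the label, the lower bound of the ALKBH3 footprint ratio, -0.365, argues against counting error hiding a fall to 0.5 of the control or less; a knockdown that changes protein alone, or unequal cell states, was not tested.

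Higher footprints of mitochondrially encoded genes were weighed last. For more mitochondria per cell, nuclear respiratory chain subunits (median 0.020, none of 60 at the mitochondrial median) and mitochondrial ribosomal proteins (-0.099) were examined. These argue against a shared rise in footprints of nuclear-encoded mitochondrial proteins. Footprints do not measure the number of mitochondria or of mitochondrial DNA copies, so more mitochondria per cell stays open. One common gain in recovery stays open: the changes ran from 1.02 to 2.56, but their heterogeneity statistic, 112.2, lay at the percentile 75.1 of random lists matched on mean count. Nuclear copies of mitochondrial genes and a change in mitochondrial translation stay open, and no test separated them.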
